A study of Rattus norvegicus with 32 samples.

How the data were processed

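RNA was measured in the red portion of the tibialis anterior muscle of 32 male Zucker rats, on 1 Affymetrix expression array per rat. The labelled RNA was prepared from 100 ng of total RNA with the GeneAtlas kit. The deposited values are log2 intensities that the authors made with RMA, which corrects the background, quantile-normalises the arrays and summarises the probes of each feature by median polish; the RMA version was not given in the sources used here. The table held 36685 features with values from 1.49 to 13.08. Array medians lay between 3.83 and 3.99, no 2 arrays were identical, and correlations between arrays ran from 0.954 to 0.994. Quantile normalisation assumes that most genes do not change, so a shift shared by most genes would have been removed before the values were deposited. RMA intensities also compress differences for dim features, where background makes up more of the signal.

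The array annotation paired 14824 features with 1 gene symbol and 829 with several, and 21032 features had no name here. Features with 1 symbol were kept, and for each gene the feature with the highest mean over all arrays was used, which left 14557 genes. The dimmest 25% of these by mean over all arrays, below a log2 value of 3.35, were left out, so 10917 genes were tested. The leptin receptor gene Lepr was not analysed here. Gene positions are not given, because the build of the array annotation was not matched to a reference.

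The arrays were grouped as labelled, 8 each from lean controls, obese controls, obese rats on the ALA diet and obese rats on the LA diet. A linear model with a mean for each group was fitted to every gene with limma 3.58.1 in R 4.3.3, with moderated variances over 28 residual degrees of freedom. P values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The replicate numbers in the titles were not used as pairs. Tables were assembled with Python 3.11.15, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.

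Gene lists of muscle pathways and of cell types that a muscle sample can hold were tested with limma's camera, which compares the members of a list with all other genes, with the correlation between members preset at 0.01. Camera with an estimated correlation and fry were run beside it. Adjustment was over the 33 lists with at least 5 tested members. Members were also counted when adjusted over the list alone. For the comparison of both oils, 95% confidence intervals of each gene's difference were taken from the limma fit. Intervals of list means were taken from the mean of the list in each rat, with the SD pooled over the 4 groups. They were not adjusted over the lists.

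The response to a diet was compared with the genotype difference across genes after dividing the obese controls into 2 sets of 4, so that no array entered both sides. All 70 ordered divisions were used. For the correlations, 100 simulations left all 4 groups without a difference, so the genotype difference was removed as well. For the share of genes that moved toward the lean level, 20 simulated draws kept the genotype difference and left both diet groups unchanged. As a test of chance, the 16 arrays of a comparison were divided into sets of 8 in 100 ways, the real one included. The same steps were tested on simulated data with 200 changed genes per simulation and 10 simulations per comparison. Changes of 0.25, 0.5, 1 and 2 log2 units were mixed in each simulation. The larger changes ease the Benjamini-Hochberg limit for the smaller ones, so the shares called can be too high for a comparison in which few genes change.

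Apart from the additions named below and in the closing sections, the comparisons, tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall among those called, the 5 with the smallest p in each direction where fewer than 5 genes were called, and up to 4 members of each list described. Symbols that start with LOC, RGD, MGC, AABR, Olr, Vom, Mir, Snor or U and digits only were passed over, and no gene is named for the comparisons of diet groups with lean controls. The rule also named Lepr, which was not analysed. Cyp1a1, its receptor targets and the hepatocyte genes fall outside the rule. Cyp1a1 was chosen after its values were seen. The hepatocyte list was added after the data were seen, and the receptor targets were not among the lists fixed before. Alternatives were no filter or a 50% filter on dim genes, every feature tested, a second quantile normalisation, centring each array on its median, a robust variance prior with trend, array weights, only the groups compared, the replicate number as a block, an adjusted p below 0.1 and each array left out in turn. Added after the data were seen were fits without obese controls 4 and 7, without LA rats 7 and 8, and without these 4 arrays, obese control 5 and ALA rat 3 together. A fit without lean control 2 and obese controls 4 and 7, the leave-one-out and second quantile normalisation of the gene lists and the simulations without ALA rat 3 or without obese controls 4 and 7 were also added then.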

Results

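The data describe RNA levels in the red tibialis anterior, the oxidative part of a hindlimb muscle, in 32 male Zucker rats, with 8 rats in each of 4 groups. Obese Zucker rats carry a mutated leptin receptor and become obese and insulin resistant, and lean Zucker rats served as the lean control. Both control groups ate the AIN-93G diet without restriction. The ALA group received this diet with 10% flaxseed oil and the LA group with 10% safflower oil, and both were pair-fed to the caloric intake of the obese controls. Flaxseed oil is rich in alpha-linolenic acid (ALA) and safflower oil in linoleic acid (LA), which has 1 double bond fewer, and the oils also differ in their other fatty acids. Feeding lasted 12 weeks and the rats were 18 weeks old at sampling. Each rat gave 1 array, values are log2 intensities, and 10917 genes were tested. With 8 arrays per group the median standard error of a difference was 0.0875 log2 units, and this number of arrays limits the precision.

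The comparison of obese with lean controls asks how the genotype alters the muscle on the same diet. Genes of slow-twitch fibres were lower in obese controls. Myh7 (feature 17702823), the slow myosin heavy chain, was at 7.48 ± 0.95 (SD, n = 8) in obese and 10.02 ± 0.25 in lean controls, 5.84-fold lower (limma, adjusted p = 0.00225). Tnnt1 (feature 17613189), slow troponin T, fell 5.72-fold from 9.55 ± 0.32 to 7.04 ± 0.74, and Tnnc1, troponin C of slow and cardiac muscle, fell 5.55-fold. Atp2a2, the calcium pump of slow and cardiac sarcoplasmic reticulum, fell 3.00-fold. In each of these 4 genes all 8 obese controls lay below every lean control. Of the 12 measured slow-twitch genes, 7 were called lower over all genes, and 7 lower and 1 higher when adjusted over the list alone, with a median log2 difference of -0.78. This list shifted downward by camera (adjusted p = 6.59e-07) and by fry (adjusted p = 0.0157), but adjusted p = 0.361 with an estimated correlation.

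Socs2 and Cish, which encode feedback inhibitors of growth hormone and cytokine signalling, were also lower, and a list of such targets was not tested. Socs2 (feature 17835345) fell 3.86-fold, from 6.30 ± 0.57 to 4.35 ± 0.36 (SD, n = 8, limma adjusted p = 0.000135), and Cish fell 3.65-fold. Other large falls were in Nrep (3.31-fold), Padi2, a peptidylarginine deiminase (3.16-fold), Mettl21cl1 (3.02-fold) and Lgi1, a secreted synaptic protein (2.77-fold). Camera did not call the insulin signalling list as a whole (adjusted p = 0.536). Its 2 called members of 21 were Socs2 and Irs1, the insulin receptor substrate, with a log2 difference of -1.01 for Irs1. The list mean differed by -0.138 (95% interval -0.232 to -0.0428) with these 2 members included, and was not computed without them. Irs1 was not called without obese controls 4 and 7 (log2 difference -0.78, adjusted p = 0.1).

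PPAR target genes and most beta-oxidation genes were higher in obese controls. Angptl4 (feature 17834433), the secreted inhibitor of lipoprotein lipase, rose 6.54-fold, from 4.15 ± 0.41 to 6.86 ± 0.57 (SD, n = 8, limma adjusted p = 2.52e-05). Pdk4 (feature 17789572), which restrains the pyruvate dehydrogenase complex, rose 2.54-fold, from 10.25 ± 0.45 to 11.60 ± 0.11. Ucp3, the mitochondrial carrier of muscle, rose 3.12-fold, and Cpt1a, which passes fatty acids to carnitine, rose 1.78-fold. These are the 4 called members of the 18 measured PPAR target genes, of which 17 were higher and 9 were called higher when adjusted over the list alone. The list had a median log2 difference of 0.29 and shifted upward by camera (adjusted p = 4.92e-11) and fry (adjusted p = 0.00519), with adjusted p = 0.181 with an estimated correlation. In beta-oxidation 18 of 21 genes were higher, and Cpt1a, Decr1 (log2 0.67) and Acadl (log2 0.35), the reductase for unsaturated chains and the long-chain dehydrogenase, were called, while Echs1, a hydratase of the same pathway, was at -0.41. Adjusted over the list alone, 4 were higher and 1 lower. Echs1 lost its call without lean control 4 (adjusted p = 0.0557) or obese control 4 (adjusted p = 0.0521). The beta-oxidation list was called upward by camera (median 0.12, adjusted p = 3.97e-05), with adjusted p = 0.444 with an estimated correlation. Its median was 0.22 without obese control 7 and 0.0783 without obese control 8. The 95% interval of its mean difference held both signs (-0.00648 to 0.36), while that of the PPAR list did not (0.344 to 0.759). The fatty acid uptake list was not called (8 of 13 higher, camera adjusted p = 0.138), except without obese controls 4 and 7 (median 0.28, adjusted p = 0.00558). Among its genes Gpihbp1, which anchors lipoprotein lipase in capillaries, was called higher (log2 0.57, adjusted p = 0.0169), and Vldlr, the very low density lipoprotein receptor, lower (log2 -0.39, adjusted p = 0.0284). Vldlr lost its call without lean control 4 (0.0608), 6 (0.0642) or 8 (0.066) or obese control 4 (0.0675) or 7 (0.0784) as adjusted p.

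**Figure D1:**
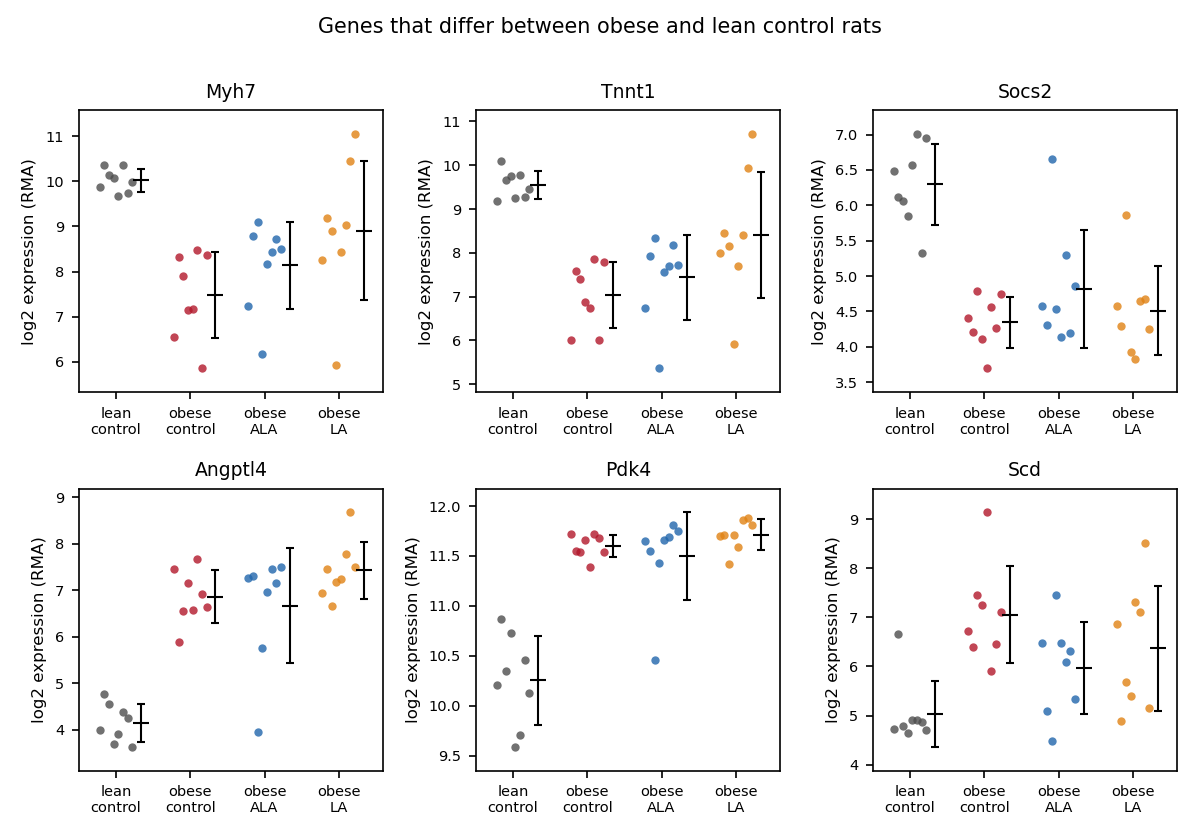
Log2 expression of 6 genes in each rat (points, 8 per group) with the group mean and SD (bars) for lean controls, obese controls and obese rats on the ALA or LA diet. Myh7, Tnnt1 and Socs2 were lower and Angptl4, Pdk4 and Scd higher in obese than in lean controls.

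Other large rises were in Scd, stearoyl-CoA desaturase (4.07-fold, from 5.03 ± 0.67 to 7.05 ± 0.98, n = 8), Mc5r, a melanocortin receptor (2.89-fold), Tpd52l1 (2.34-fold), Asb4, a substrate adaptor of ubiquitin ligases (2.18-fold), Lyz2, the lysozyme of macrophages (2.00-fold), Oas1k of the interferon-induced synthetases (1.94-fold) and Fkbp5, a glucocorticoid-induced co-chaperone (1.89-fold). Scd was at 9.14 in obese control 5, in which liver transcripts were abundant, against 5.90 to 7.45 in the other obese controls. The Lyz2 call was lost without obese control 4 (log2 0.86, adjusted p = 0.0568). The Fkbp5 call was lost without any 1 of 11 arrays, namely lean controls 1, 3, 5, 6, 7 and 8 and obese controls 1, 2, 3, 6 and 8 (adjusted p from 0.0516 to 0.103). In all, limma called 192 of 10917 genes, 47 higher and 145 lower, of which 22 changed by at least 1 log2 unit. The balance of directions moved with the scaling: 24.5% of the called genes were higher as deposited, 36.9% after a second quantile normalisation and 45.2% with each array centred on its median.

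Fibroblast markers, some matrix genes and part of the endothelial markers were lower in obese controls. Col15a1 and Col3a1, collagens of basement membrane zones and of fibrils, had log2 differences of -0.90 and -0.81, and Serpinh1, the collagen chaperone, of -0.44. These were the 3 called of 25 matrix genes, with 6 lower when adjusted over the list alone. The matrix list median was -0.26 (camera adjusted p = 7.76e-05, and adjusted p = 0.444 with an estimated correlation). The 95% interval of its mean difference held both signs (-0.582 to 0.156). Those of fibroblast (-0.544 to -0.0325) and endothelial markers (-0.419 to -0.0176) did not. Of 11 fibroblast markers 10 were lower and 1, Cd34 of stromal and vessel cells, was called (log2 -0.72), also when adjusted over the list alone, with a list median of -0.24 (camera adjusted p = 0.000555). Of 9 endothelial markers 6 were lower, and Tie1 (log2 -0.57) and Cdh5 (log2 -0.53), a receptor and the cadherin of vessel lining, were called, and 4 when adjusted over the list alone (list median -0.19, camera adjusted p = 0.0058). Both list tests had adjusted p = 0.444 with an estimated correlation, and the endothelial median was -0.10 without obese control 4. Tie1 lost its call without lean control 6 (adjusted p = 0.0507), and Cdh5 without lean control 6 (0.0677) or 8 (0.052) or obese control 4 (0.0617) or 7 (0.066) as adjusted p. Neither was called without obese controls 4 and 7 together (log2 -0.41 and -0.40, adjusted p = 0.118 and 0.15). Smooth muscle and pericyte markers did not shift (4 of 8 lower, camera adjusted p = 0.979).

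In the list of branched-chain amino acid breakdown, 18 of 19 genes were lower and the median log2 difference was -0.23 (camera adjusted p = 8.62e-08, fry adjusted p = 0.0331). The list had adjusted p = 0.444 with an estimated correlation. The called members were Bdh1 (log2 -1.31) and Oxct1 (log2 -0.57), which serve ketone body use, Dbt (log2 -0.40), a subunit of the branched-chain ketoacid dehydrogenase, and Bckdk (log2 0.28), the kinase that inhibits it. Adjusted over the list alone, 12 were lower and 1 higher. Dbt was not called without obese control 7 (adjusted p = 0.0511). All 36 oxidative phosphorylation genes were lower, none called alone, with a median of -0.13 (camera adjusted p = 1.51e-07), and 12 of 15 genes of glucose uptake and glycolysis were lower with a median of -0.22 (camera adjusted p = 0.00149). In the glycolysis list Ldhb, the lactate dehydrogenase subunit of oxidative tissue, was called at -1.31, and 2 genes were when adjusted over the list alone. Macrophage markers were higher in 14 of 15 genes (median 0.22, camera adjusted p = 0.000253), with Lyz2 called and 5 when adjusted over the list alone. These 3 lists had adjusted p = 0.444 with an estimated correlation. Without obese control 7 the medians of oxidative phosphorylation and glycolysis were -0.0632 and -0.13.

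Obese controls 4 and 7 stood apart from their group. Their mean over the myogenesis and denervation genes was 7.14 and 7.26, against 6.02 to 6.18 in the other obese controls, but lean control 2 was as high (7.13), and their macrophage marker means were 5.91 and 6.17. Without these 2 arrays the called lists numbered 11, of which 8 were among the 15 called with all arrays, and the medians of oxidative phosphorylation (-0.0144), glycolysis (-0.00965), macrophage markers (0.0649) and endothelial markers (-0.0846) were not called, nor were those of the tricarboxylic acid cycle, fast-twitch and atrophy lists. The slow-twitch, PPAR, beta-oxidation, branched-chain, matrix and fibroblast lists were called with and without them. With lean control 2 also left out 12 lists were called, 8 of them among the 15, and the medians of oxidative phosphorylation (-0.0294), glycolysis (-0.0502), macrophage markers (0.0538) and endothelial markers (-0.10) were again not called. The genes called numbered 164 without obese controls 4 and 7 and 133 with lean control 2 also left out. Calls of Lyz2, Irs1, Dbt, Echs1 and Vldlr were lost without obese controls 4 and 7 (adjusted p = 0.12, 0.1, 0.113, 0.118 and 0.166). The other 5 called lists each lost the call without some single array. Without obese control 4 or 7 this held for the tricarboxylic acid cycle (median -0.13 with all arrays, adjusted p = 0.0513 and 0.145 without) and fast-twitch genes (median -0.11, adjusted p = 0.0958 and 0.145), the latter also without lean control 7 (adjusted p = 0.0509), and without obese control 7 their medians were -0.0622 and -0.069. Adipocyte markers (median 0.24) lost it without obese control 5 (adjusted p = 0.0578). The list of atrophy genes (median 0.15) lost it without lean control 5 or 7 or obese control 4, 6, 7 or 8 (adjusted p from 0.0509 to 0.0958). Glucocorticoid targets (median 0.12) lost it without lean control 5, 6, 7 or 8, obese control 2 or 6, or LA rat 5 or 8 (adjusted p from 0.0501 to 0.187). These 5 lists had adjusted p = 0.444 with an estimated correlation, except 0.524 for the tricarboxylic acid cycle.

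**Figure D2:**
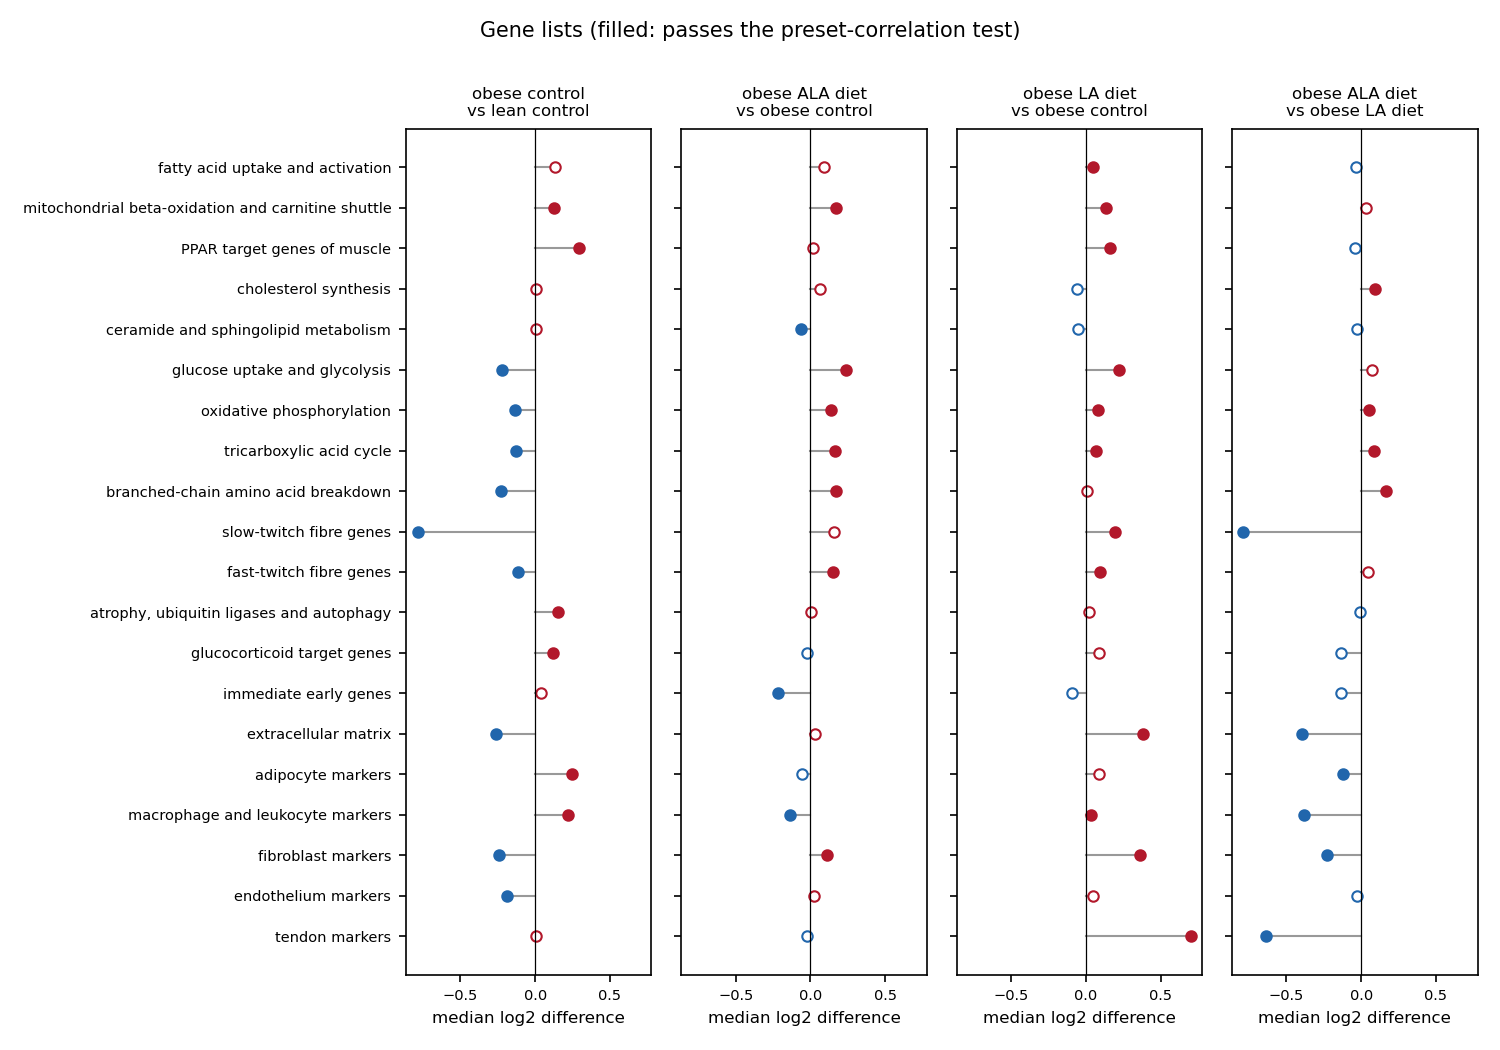
Median log2 difference of the members of 20 gene lists in 4 comparisons, with filled points where camera with the preset correlation called the list and open points where it did not. The slow-twitch median was -0.78 in obese against lean controls, and in ALA against LA rats it was -0.79 with all rats and -0.19 without LA rats 7 and 8.

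In obese rats on flaxseed oil, no gene passed the test against obese controls. The genes nearest to it included Lyz2, at 7.12 ± 0.49 (SD, n = 8) on the ALA diet and 8.11 ± 0.75 in obese controls, 2.00-fold lower (limma adjusted p = 0.348), and Rbm3, a cold-induced RNA-binding protein, at a log2 difference of -0.61. The log2 difference of Lyz2 was -0.60 without obese controls 4 and 7 and -0.45 without 6 arrays (obese controls 4, 5 and 7, LA rats 7 and 8 and ALA rat 3), and that of Rbm3 was -0.39 without obese controls 4 and 7. Srebf1, the regulator of fatty acid synthesis, was 1.73-fold higher (adjusted p = 0.354), and Gja3, a connexin, Klhl21, an adaptor of ubiquitin ligases, Dbt and Rtl6 had differences of 0.40, 0.41, 0.39 and 0.29. Or11g27, Hnrnpl-ps2 and Ermp1 were at -0.49, -0.41 and -0.33. Limma called 0 genes, with 918 at an unadjusted p below 0.05, and also 0 with array weights or with a robust prior. Simulated changes of 0.5 log2 units were called in 84.6% of genes and of 0.25 in 25.4% in this comparison. These shares hold for 200 changed genes with changes of up to 2 log2 units among them. They can be too high where few genes change, so they do not exclude changes of 0.5.

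Lists of energy metabolism were higher on the ALA diet by camera with the preset correlation, but fry called 0 of the 33 lists. Of 19 branched-chain amino acid genes 17 were higher, with a median of 0.17 (camera adjusted p = 2.27e-09), and 3 were called when adjusted over the list alone, with Dbt at 0.39 and Mmut, methylmalonyl-CoA mutase, at 0.29. All 8 fast-twitch genes were higher (median 0.15, camera adjusted p = 5.89e-05), 2 of them when adjusted over the list alone, with Actn3, the actinin of fast fibres, at 0.34. Oxidative phosphorylation (35 of 36 genes, median 0.14), the tricarboxylic acid cycle (19 of 20, median 0.17), beta-oxidation (20 of 21, median 0.17) and glycolysis (13 of 15, median 0.24) shifted the same way with no member called, also when adjusted over the list alone. Immediate early genes (median -0.22) and macrophage markers (median -0.14, with Fcer1g at -0.55 and Tyrobp at -0.45, parts of Fc receptor signalling) shifted downward, with 0 and 4 members lower when adjusted over the list alone. Fibroblast markers (median 0.11) were called upward and ceramide genes (median -0.0619, with the ceramide synthase Cers6 at -0.45) downward, each with 1 member when adjusted over the list alone. All 10 lists had adjusted p = 0.531 to 0.549 with an estimated correlation.

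Without obese controls 4 and 7, 7 lists were called, and 4 of the 10 were among them: the branched-chain (median 0.13), fast-twitch (0.0574), immediate early (-0.12) and fibroblast lists (0.14). The median of oxidative phosphorylation was then -0.00451, and those of the other 5 lists were not called. Of the list members named above, Fcer1g was then at -0.27, Tyrobp at -0.14, Actn3 at 0.12 and Mmut at 0.16, and without the 6 arrays Cers6 was at -0.19. Without obese control 7 alone the medians were 0.0583 for oxidative phosphorylation, 0.0835 for the tricarboxylic acid cycle, 0.0817 for beta-oxidation, 0.14 for glycolysis, -0.0566 for macrophage markers and -0.0342 for ceramide genes. Of these 4 lists, immediate early genes lost the call without obese control 2 (adjusted p = 0.103), and fibroblast markers without obese control 1 (0.0863) or 2 (0.0615) or ALA rat 2 (0.0572) or 7 (0.148) as adjusted p. The fibroblast median was 0.0462 without ALA rat 7 and 0.20 without obese control 5. Ceramide genes lost it without obese control 4 or 7 or ALA rat 2, 5 or 7 (adjusted p from 0.0516 to 0.0753).

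In obese rats on safflower oil, none of the 10917 genes passed the test against obese controls. Casq2, calsequestrin of slow and cardiac muscle, was at 8.28 ± 0.78 (SD, n = 8) on the LA diet and 7.17 ± 0.20 in obese controls, 2.17-fold higher with 8 of 8 LA rats above every obese control (limma adjusted p = 0.252). Serpinh1, Ebf2, a transcription factor of adipocyte precursors, Scara5, a ferritin receptor of stromal cells, and Capn6 had log2 differences of 0.39, 0.40, 0.52 and 0.54. Gramd1b, a cholesterol carrier between membranes, Parm1, Fbxo31, a ubiquitin ligase subunit, Sc5d of cholesterol synthesis and Fcrlb were at -0.75, -0.83, -0.47, -0.33 and -0.38. Parm1 and Fbxo31 were at -0.46 and -0.28 without obese controls 4 and 7. Limma called 0 genes, with 682 at an unadjusted p below 0.05, and 0 with array weights or with a robust prior. Simulated changes of 0.5 log2 units were called in 84.4% of genes and of 0.25 in 25.4% here, with the same mix of sizes and the same limit.

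Camera with the preset correlation called 12 lists on the LA diet and fry called 0. All 11 fibroblast markers were higher (median 0.36, camera adjusted p = 4.81e-11), with 7 called when adjusted over the list alone, among them Pi16 at 0.45 and Dcn, decorin, at 0.39 (0.24 without LA rat 7). The fibroblast list had adjusted p = 0.0944 with an estimated correlation. Of 25 matrix genes 23 were higher (median 0.38, camera adjusted p = 6.26e-17), 12 when adjusted over the list alone, with Col3a1 at 0.67 and Fbn1, fibrillin, at 0.60. The matrix list had adjusted p = 0.183 with an estimated correlation. Slow-twitch genes (10 of 12 higher, median 0.20, 5 higher and 1 lower when adjusted over the list alone, with Myh7 at 1.42 and Tnnt1 at 1.37) and tendon markers (7 of 8, median 0.70, none when adjusted over the list alone) were called as well, with adjusted p = 0.622 for both with an estimated correlation. LA rats 7 and 8 stood apart here: their slow-twitch means were 8.88 and 9.68 against 7.01 to 7.93 in the other LA rats, and their tendon means were 7.93 and 6.28 against 4.14 to 5.36. Without these 2 rats the slow-twitch median was -0.0148 and the tendon median -0.0574, while the matrix (0.11) and fibroblast (0.20) lists were still called. Myh7, Tnnt1 and Dcn were then at 0.81, 0.73 and 0.16, and without the same 6 arrays as above Myh7 and Tnnt1 were at 0.36 and 0.44. Tendon markers lost the call without LA rat 7 alone (median 0.16, adjusted p = 0.205) and had a median of 0.41 without LA rat 8. Without LA rat 7 the matrix and fibroblast medians were 0.21 and 0.24. The slow-twitch median was 0.0672 without LA rat 8 and 0.12 without LA rat 7, and 0.30 to 0.49 without LA rat 3 or 5 or obese control 4 or 7.

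Beta-oxidation, PPAR targets, fatty acid uptake, glycolysis, oxidative phosphorylation, the tricarboxylic acid cycle, fast-twitch genes and macrophage markers were also called upward on the LA diet, with medians of 0.14, 0.16, 0.0512, 0.22, 0.079, 0.067, 0.0952 and 0.0375. Adjusted over the list alone, 3 macrophage markers were higher and no member of the other 7 was called. They had adjusted p = 0.622 with an estimated correlation, or 0.682 for oxidative phosphorylation and the tricarboxylic acid cycle. Most of these shifts depended on single rats. Oxidative phosphorylation (median -0.0588, adjusted p = 0.000832) and the tricarboxylic acid cycle (median -0.0652, adjusted p = 0.0137) were called downward without obese controls 4 and 7, and glycolysis and beta-oxidation had medians of -0.0585 and -0.0164. Without the same 6 arrays as above oxidative phosphorylation was again called downward (median -0.0418, adjusted p = 0.0235). Without obese control 7 alone 5 of the 12 lists were called, and the first 7 named here lost the call (adjusted p from 0.0636 to 0.882), with medians of 0.00223 for oxidative phosphorylation and 0.00155 for the tricarboxylic acid cycle, and of 0.0468 to 0.0946 for the other 5.

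Without obese control 4, fatty acid uptake, glycolysis, oxidative phosphorylation and the tricarboxylic acid cycle lost the call (adjusted p from 0.0749 to 0.293), as did both of the last without LA rat 1 (0.0868 and 0.125), PPAR targets without LA rat 7 (0.14), and fatty acid uptake without obese control 3 or 5 or LA rat 1, 2, 3, 4, 6 or 7 (0.0548 to 0.133). The medians without obese control 4 were 0.14 for glycolysis, 0.0363 for oxidative phosphorylation and 0.0276 for the tricarboxylic acid cycle. Oxidative phosphorylation was at 0.0481 without LA rat 1, the tricarboxylic acid cycle at 0.10 without obese control 1, and PPAR targets at 0.0806 without LA rat 7. The fatty acid uptake median was 0.0834 to 0.12 without obese control 1, 5, 6 or 8 or LA rat 1, 5 or 7.

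Macrophage markers moved both ways on the LA diet, from a median of 0.0375 with all arrays. They lost the call without obese control 1, 2, 6 or 8 or LA rat 7 (medians 0.00554 to 0.0247, adjusted p from 0.0611 to 0.176). They were higher without obese control 7 (median 0.19) or 4 (0.14), and without both the median was 0.32 (adjusted p = 5.77e-12). The median was 0.0568 to 0.10 without obese control 3 or 5 or LA rat 1, 2, 4 or 5, and 0.29 without the same 6 arrays as above (adjusted p = 9.52e-11).

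Cyp1a1 (feature 17844555), a cytochrome P450 induced through the aryl hydrocarbon receptor, was higher on the LA diet. It was chosen after its values were seen, and at a mean of 3.27 it was among the dim genes left out. The means of the other 3 groups lay below the limit of 3.35 for dim genes, so the size of its difference is uncertain and no fold is given. Its level was 3.77 ± 0.29 (SD, n = 8) on the LA diet, 3.11 ± 0.08 in obese controls, 3.13 ± 0.14 on the ALA diet and 3.09 ± 0.16 in lean controls, and all 8 LA rats lay above every obese control and every ALA rat. Without the filter, over 14557 genes, it was the 1 gene called against obese controls (log2 difference of the deposited values 0.66, SE 0.0905, limma adjusted p = 0.000326), and the 1 gene called between the oils, with a log2 difference of the deposited values of -0.64 for ALA against LA (adjusted p = 0.000617). Over every feature the adjusted p values were 0.00133 and 0.00247, and without any single array the adjusted p against obese controls was at most 0.00145.

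**Figure D3:**
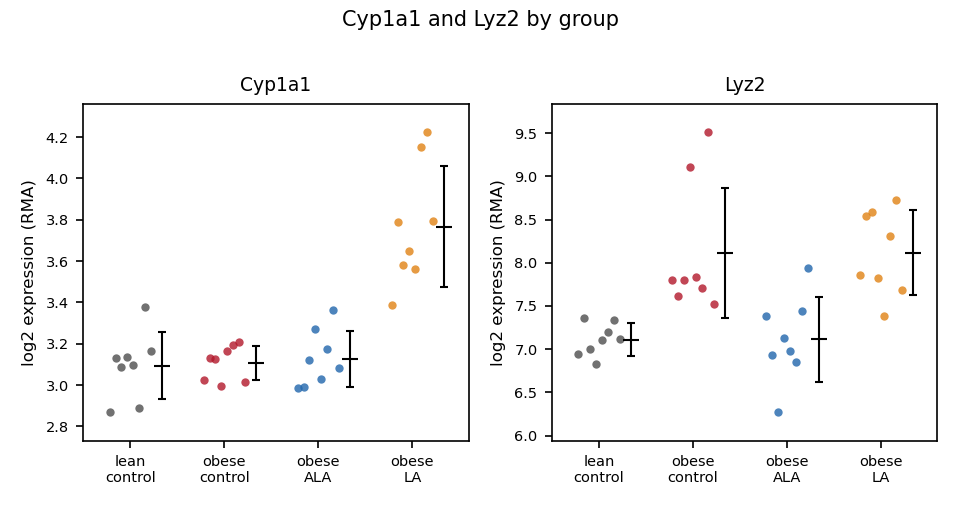
Log2 expression of Cyp1a1 and Lyz2 in each rat (points, 8 per group) with the group mean and SD (bars). All 8 LA rats lay above every other obese rat for Cyp1a1, and Lyz2 averaged 8.11 in obese controls and LA rats and 7.12 in ALA rats.

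The direct comparison of the oils, at the same added share and feeding time, asks whether the fatty acid supplied makes a difference. No tested gene passed. Lyz2 averaged 7.12 ± 0.49 (SD, n = 8) on the ALA and 8.11 ± 0.49 on the LA diet, 2.00-fold lower with ALA (limma adjusted p = 0.46). Without obese controls 4 and 7, which enter through the shared spread, Lyz2 was called (adjusted p = 0.0288). Cxcl16, a chemokine of macrophages, Scarf2, a scavenger receptor family member, Ticam2, an adaptor of Toll-like receptors, and Dapp1 were at -0.56, -0.36, -0.31 and -0.27. Zdhhc9, a palmitoyltransferase, Gja3, Exosc5 of the RNA exosome, Immp2l, a mitochondrial peptidase, and Zfyve26 were at 0.40, 0.35, 0.30, 0.30 and 0.27. Limma called 0 genes, with 758 at an unadjusted p below 0.05, and 0 with array weights or with a robust prior. The 95% interval of the difference lay within 1 log2 unit of 0 for 10814 genes (99.06%) and within 0.5 for 10196 (93.4%). Simulated changes of 0.5 were called in 85.2% of genes, with the mix of sizes and the limit given for the other diet comparisons.

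All 15 macrophage and leukocyte markers were lower with ALA than with LA (median -0.38, camera adjusted p = 1.2e-10), 8 of them when adjusted over the list alone. Among them were Fcer1g (-0.58), Tyrobp (-0.49) and C1qb of complement (-0.63), and the list mean differed by -0.37 (95% interval -0.63 to -0.12). All 19 branched-chain amino acid genes were higher with ALA (median 0.17, camera adjusted p = 3.73e-12), 5 when adjusted over the list alone, with Mmut at 0.30, Bcat2, the transaminase, at 0.35 and Ivd, isovaleryl-CoA dehydrogenase, at 0.23, and a mean difference of 0.20 (95% interval 0.0641 to 0.33). Of 15 cholesterol synthesis genes 11 were higher (median 0.0903, camera adjusted p = 0.00224), 2 when adjusted over the list alone, with Sc5d at 0.29 and Hsd17b7 at 0.27, and a mean difference of 0.0996 (95% interval 0.035 to 0.16). All 25 matrix genes were lower with ALA (median -0.40, with Fbn1 at -0.49), none when adjusted over the list alone. Their mean difference was -0.42 (95% interval -0.79 to -0.0509). This interval pools the SD over the 4 groups, while the matrix SD was 0.599 on LA and 0.234 on ALA. It therefore does not show a difference from 0 by itself. The matrix median was -0.22 without LA rat 7, whose matrix mean of 7.48 compares with 5.52 to 6.63 in the other LA rats, and the cholesterol median was 0.0593 without LA rat 2. These 4 lists had adjusted p = 0.185 with an estimated correlation, fry called 0 lists, and no single array ended the camera calls of these 4. C1qb was at -0.32 without LA rats 7 and 8.

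Slow-twitch genes were lower with ALA (10 of 12, median -0.79, with Casq2 at -0.93), as were tendon, fibroblast and adipocyte markers (8 of 8, 10 of 11 and 9 of 9, medians -0.63, -0.23 and -0.12). Adjusted over the list alone 2 slow-twitch genes and none of the others were lower, and with an estimated correlation these had adjusted p = 0.373, 0.492, 0.377 and 0.424. Oxidative phosphorylation (34 of 36) and the tricarboxylic acid cycle (18 of 20) were higher with ALA, with medians of 0.0539 and 0.0837, none when adjusted over the list alone, and adjusted p = 0.788 with an estimated correlation. The 95% intervals of their mean differences held both signs (-0.109 to 0.229 and -0.0833 to 0.228). So did those of tendon (-1.4 to 0.233) and adipocyte markers (-0.355 to 0.0681). Those of slow-twitch genes (-1.12 to -0.0739) and fibroblast markers (-0.515 to -0.00284) did not. However, the SD behind them was pooled over the 4 groups, and the spread was larger on LA than on ALA. The SDs were 0.839 and 0.358 for slow-twitch genes and 0.434 and 0.181 for fibroblast markers. Intervals from the SDs of these diet groups alone were not computed. The bounds therefore do not show a difference from 0 by themselves. Without LA rats 7 and 8 only 4 lists were called, the macrophage (-0.22), branched-chain (0.13), cholesterol (0.0664) and matrix (-0.13) lists. The tendon median was then 0.0365, and the slow-twitch median was -0.19 (adjusted p = 0.68), with Casq2 at -0.60. Without LA rat 7 alone 6 of the 10 were called, and tendon (adjusted p = 0.313), fibroblast (0.0694), adipocyte (0.446) and tricarboxylic acid cycle genes (0.0559) were not. Adipocyte markers also lost the call without ALA rat 2 (0.0563) or LA rat 6 (0.0617), and oxidative phosphorylation and the tricarboxylic acid cycle without ALA rat 1 (0.112 and 0.0744) or 6 (0.0829 and 0.0669) or LA rat 5 (0.166 and 0.106), oxidative phosphorylation also without LA rat 8 (0.179), all as adjusted p. Medians that moved by over 1.5 times were those of tendon (-0.18), fibroblast (-0.13) and adipocyte markers (-0.0763) without LA rat 7, slow-twitch genes without LA rat 8 (-0.47), adipocyte markers without ALA rat 4 (-0.19) and the tricarboxylic acid cycle without LA rat 5 (0.0557). Oxidative phosphorylation was at 0.0266 to 0.0352 without ALA rat 6 or LA rat 5 or 8 and at 0.0814 without ALA rat 3.

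Whether the diets moved muscle RNA toward the lean state was asked across the 10917 genes, which are not independent replicates. With the obese controls divided so that no array was shared, the ALA response had a median Pearson r of -0.25 with the genotype difference. The range over 70 divisions was -0.39 to 0.0528, and none of 100 simulations gave so low a median. In these simulations no group differed, so the genotype difference was absent as well. They do not show which values an unchanged diet gives beside the real genotype difference. The LA response had a median r of -0.12 (range -0.26 to 0.23), and 21 of 100 simulations were as low. A median of 69.2% of the genotype genes moved toward the lean level on the ALA diet (range 42.4 to 86.7) and 56.7% on the LA diet (range 33.2 to 70), while simulated unchanged groups gave medians of 45.3% and 48.1%, with 0 and 4 of 20 draws as high. A difference between the diets in these shares was not tested. The ALA values did not exceed the simulations in every set of rats. Without ALA rat 3 the median r was -0.22 and the share 61.8%, and simulations of groups of these sizes were as low in 8 of 100 and as high in 4 of 20 draws. Without obese controls 4 and 7 they were -0.0781 and 63.2%, with 22 of 100 as low and 2 of 20 as high, and without the same 6 arrays as above -0.023 and 53.1%.

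A relation between the responses to both oils was not shown. Once the obese controls were divided the median r was 0.11 across genes (range -0.31 to 0.32), and 17 of 100 simulations were as high. The median was -0.0326 without obese controls 4 and 7 and 0.22 without LA rats 7 and 8. With all 8 obese controls in both responses r was 0.56, against a simulated median of 0.52 for groups that share a control without any response. Their covariance was 0.0104, which exceeded the simulated median of 0.00629 by 0.00415 and lay below the highest simulated value of 0.012. No gene was called in either response, so the overlap of calls was 0 where 0 were expected.

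Against lean controls, 97 genes were called in ALA rats (35 higher, 62 lower) and 177 in LA rats (75 higher, 102 lower). These numbers were 313 and 369 with array weights, 252 and 183 with only the groups compared, and 155 and 294 without obese controls 4 and 7. The PPAR target list was called in both, with medians of 0.44 and 0.45 and 16 and 17 of 18 genes higher, and held with an estimated correlation (adjusted p = 0.0152 and 0.0187). Of its members 4 and 6 were called over all genes, and 14 and 13 when adjusted over the list alone. Slow-twitch genes were lower in both (medians -0.77 and -0.48), with camera adjusted p = 4.29e-11 and 0.0115, and adjusted p = 0.0654 and 0.524 with an estimated correlation. Of these 12 genes 5 and 0 were called lower over all genes, and 9 and 6 when adjusted over the list alone. The number called in ALA rats was 50 to 64 without any 1 of 7 arrays: lean control 4 (57), 6 (61) or 8 (51) or ALA rat 4 (52), 5 (55), 6 (64) or 7 (50), and the number in LA rats was 110 without lean control 6. After a second quantile normalisation 48.6% and 51.2% of the called genes were higher, against 36.1% and 42.4% as deposited, and with centred arrays 62.4% and 58.4%.

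**Figure D4:**
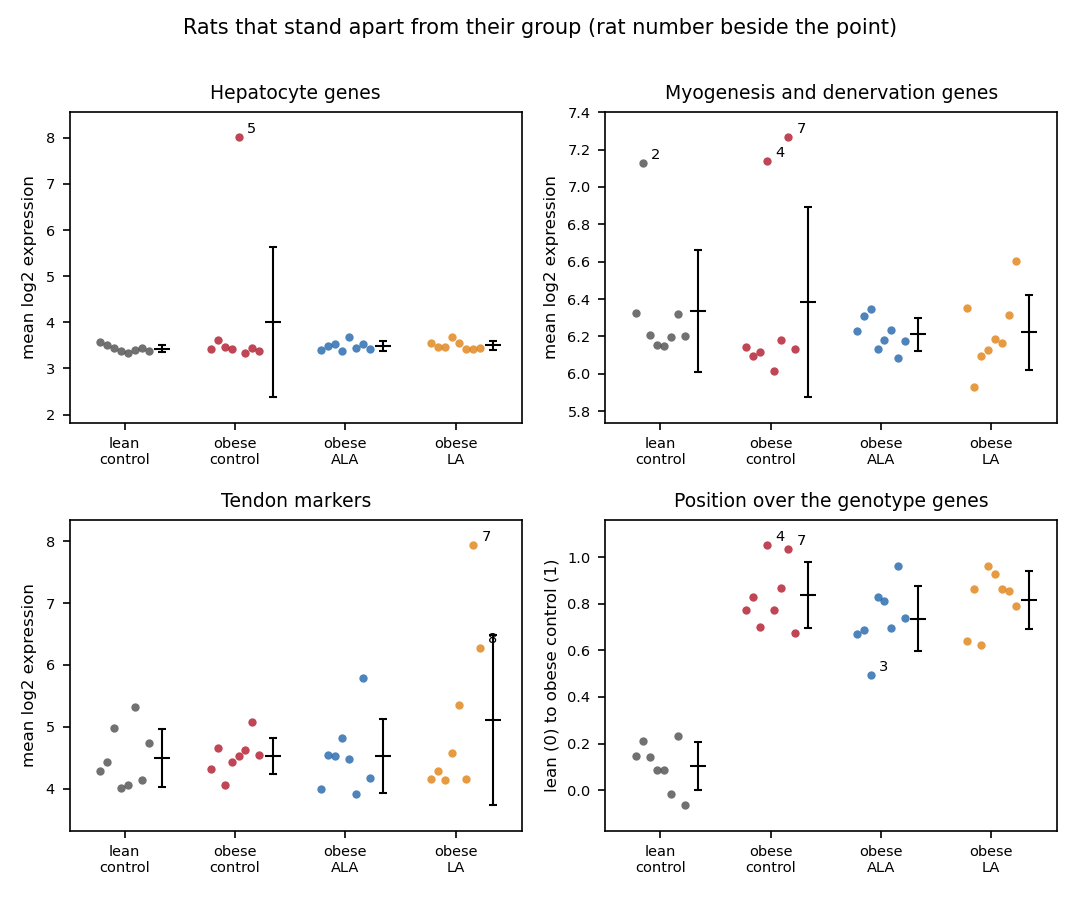
Mean log2 expression of hepatocyte genes, of myogenesis and denervation genes and of tendon markers in each rat (points, 8 per group), with its position from lean (0) to obese control (1) over the genotype genes and the group mean and SD (bars). Numbers name rats that stand apart: obese control 5 for hepatocyte genes, obese controls 4 and 7 and lean control 2 for denervation genes, LA rats 7 and 8 for tendon markers, and ALA rat 3 (position 0.493).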

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

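The test of a wrong label for ALA rat 3 and the comparison of lean shares were chosen after its values were seen. Single rats stood far from the other 7 of their group in 7 of 166 groups tested, where chance gives about 8.3, or 1 in 20. Scd, the desaturase that rose with the obese genotype, was at 6.662 in lean control 2 and at most 4.917 in the other lean controls. In ALA rat 3, Klhl21 was at 8.416, above 8.062 in the nearest rat, and Hsd17b7 of cholesterol synthesis was at 4.498, below 4.774. Tyrobp, a signalling partner of Fc receptors, was highest in ALA rat 8 at 6.097 (nearest 5.758). In LA rats, Ebf2 was lowest in rat 1 at 3.933 (nearest 4.161), Scara5 highest in rat 7 at 5.99 (nearest 5.233), and Zdhhc9 highest in rat 5 at 4.97 (nearest 4.741).

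ALA rat 3 had 2 of these 7 values, and it also lay nearest to lean controls over the genotype genes. On a scale from lean (0) to obese control (1) it was at 0.493, while lean controls ran from -0.0619 to 0.233, obese controls from 0.673 to 1.05 and the other 15 diet rats from 0.624 to 0.962. This position argues against a lean rat under a wrong label. Lean RNA mixed into the sample was neither shown nor excluded: the residual SD after 1 mixing share was 1.28, exceeded only by LA rats 7 and 8 (1.55 and 1.49) among the other diet rats. Angptl4 (3.939), Pdk4 (10.46), Scd (4.49) and Socs2 (6.654) were near or beyond the lean means while Myh7 (9.089) and Tnnc1 (7.34) lay between, and the lean share was 0.837 over genes higher in obese controls and 0.356 over genes lower in them, a gap of 0.481 where other diet rats ran from -0.491 to 0.439. No biological explanation was tested.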

How the results depend on the processing

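The fits without named sets of rats, and the single-array omissions and second quantile normalisation of the gene lists, were chosen after the data were seen. Named genes kept direction and side of the threshold in 1398 values across settings, lost the call in 35, gained it in 1 and reversed in 0, and lists did so in 305, 142, 0 and 21. All 35 lost calls were in obese against lean controls. The genes named in the diet comparisons had not passed, so they had no call to lose. Leaving out each array in turn, the genes called numbered 142 to 223 in obese against lean controls, 50 to 120 in ALA and 110 to 241 in LA rats against lean controls, and 0 in the 3 diet comparisons. Lists numbered 12 to 15 in obese against lean controls, 8 to 12 on ALA, 5 to 14 on LA and 6 to 13 between the oils. Replicate numbers were not taken as pairs, since only 17 of 48 same-number correlations exceeded 0.1. However, 13 of 48 rats matched their own number best, which is more than random matching gives. Obese controls and ALA rats had 5 of 8 for each, with a mean of 0.112 against -0.015 for other numbers. Pairing by number is therefore not excluded. With the replicate number as a fixed or random block, 245 and 214 genes were called in obese against lean controls and 0 in each diet comparison, with 10, 12 and 11 diet lists under the fixed block. The divisions and simulations do not use these numbers. In obese against lean controls, fast-twitch genes and adipocyte markers lost the call after a second quantile normalisation, and fast-twitch genes and glucocorticoid targets with centred arrays. On LA 2 lists lost it after a second quantile normalisation. With the 50% filter 2 lists lost it in obese against lean controls, 2 on ALA, 1 on LA and 1 between the oils. In obese against lean controls 2 also lost it without a filter and 1 with the fixed block. RMA intensities near the background, such as those of Cyp1a1, limit the size of a change that can be read.

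Array weights gave 316, 313 and 369 genes in obese controls, ALA and LA rats against lean controls, and an adjusted p below 0.1 gave 354, 171 and 320, where a wider threshold calls more by construction. Only the groups compared gave 252 in ALA rats against lean controls. No filter and every feature each gave 1 gene, Cyp1a1, on LA against obese controls and 1 between the oils, because the filter removes it. Camera with an estimated correlation called 0 lists in each of the 4 main comparisons, and fry 3, 0, 0 and 0, where the preset correlation called 15, 10, 12 and 10. Limma had 1616, 918, 682 and 758 genes at an unadjusted p below 0.05 there.

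With all 8 obese controls on both sides, the correlations with the genotype difference were -0.596 for ALA and -0.451 for LA, that between the responses was 0.559, and 84.6% and 77.8% of genotype genes moved toward lean, since a shared control produces this by construction. Without ALA rat 3 the values were -0.216, -0.12, 0.129, 61.8% and 56.7%.

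For the rest the cause was not tested. Without obese controls 4 and 7, 1 gene was called between the oils (Lyz2), and 155 and 294 in ALA and LA rats against lean controls. The ALA correlation was -0.0781, the LA correlation -0.0283, and that between the responses reversed to -0.0326. Oxidative phosphorylation reversed on ALA (-0.00451), and on LA so did beta-oxidation (-0.0164), glycolysis (-0.0585), oxidative phosphorylation (-0.0588) and the tricarboxylic acid cycle (-0.0652), the last 2 of them called downward. With lean control 2 also left out, 133, 121 and 256 genes were called in obese controls, ALA and LA rats against lean controls. Without LA rats 7 and 8, the correlation between the responses was 0.216, and 146 genes were called in ALA rats against lean controls and 4 lists between the oils. Slow-twitch genes (-0.0148) and tendon markers (-0.0574) reversed on LA, and tendon markers between the oils (0.0365). Without obese controls 4, 5 and 7, LA rats 7 and 8 and ALA rat 3, 263 and 317 genes were called in ALA and LA rats against lean controls and 7 lists on LA. The correlations were -0.023, 0.0245 and -0.0104, and 53.1% of genes moved toward lean on ALA. Reversed were glycolysis (0.0247), oxidative phosphorylation (0.0174), the tricarboxylic acid cycle (0.0245) and fast-twitch genes (0.011) in obese against lean controls, and oxidative phosphorylation (-0.00783) and macrophage markers (0.0393) on ALA. On LA these were fatty acid uptake (-0.00503), beta-oxidation (-0.0238), PPAR targets (-0.0235), glycolysis (-0.0699), oxidative phosphorylation (-0.0418) and the tricarboxylic acid cycle (-0.0451), and between the oils tendon markers (0.0462).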

Other observations

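The tests of liver RNA in obese control 5, of slow-twitch genes without obese controls 4, 5 and 7 and of receptor targets with genes or rats left out were chosen after the results were seen. Liver transcripts were abundant in obese control 5: albumin (Alb) was at 11.83 against 4.531 to 6.54 in the other obese controls, and Tf, Gc, Hp and Ttr, which encode plasma proteins, were at 11.02, 9.983, 9.902 and 9.589. All 21 measured genes of a list of 32 hepatocyte genes, or 100%, lay more than 1 log2 unit above the highest other obese control. Of the other 10908 tested genes 84, or 0.77%, did so, against at most 0.0366% of all genes for another obese control, which argues against an array that scatters all genes. Liver RNA carried into this sample is a candidate explanation. Of the 21 genes 9 were among those tested and 1 was also in another list, and no biological explanation was tested.

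The fall of slow-twitch genes in obese controls did not rest on the arrays that stood apart. Without obese controls 4, 5 and 7 the median of the 12 genes was -0.865, against -0.783 with all, and 5 of the 7 called members kept the call. Over 32 rats with group means removed, Tnnt1 correlated with the other slow-twitch genes (r = 0.801, permutation p = 2e-05, and 0.666 without the 2 farthest rats). Within groups r was 0.9 in lean controls, 0.837 on ALA, 0.948 on LA and 0.253 in obese controls, the group whose genes were lower. All 8 obese controls, at list means of 6.793 to 7.957, lay below the lean controls at 8.137 to 9.036. A less red portion sampled from obese rats and a different fibre composition cannot be told apart, because the sampled portion was not measured and both would lower these genes together.

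As a hypothesis, the other genotype genes may follow slow-fibre content. The slope on the slow-twitch score within groups accounted for a median share of 0.00113 of the genotype difference (95% interval -0.0768 to 0.0972, 185 genes), and for at least 0.5 in 3 genes. By this slope most of these calls did not follow the score. The slope was pooled over the groups, and the score varied most in LA rats (SD 0.839, against 0.286 to 0.358 in the other groups). It was not computed without LA rats 7 and 8, which had the highest scores of their group. Fibre content is therefore not excluded as a source.

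A second hypothesis was that Cyp1a1 rises on the LA diet with other targets of the aryl hydrocarbon receptor. Of 8 listed targets 5 were measured, 3 of them higher on LA. The log2 differences from obese controls were 0.29 for Aldh3a1, 0.20 for Ahrr and 0.0373 for Cyp1b1. Nqo1 and Nfe2l2 were at -0.18 and -0.0937, and none of the 5 was called. The mean difference of the 5 targets was 0.0519 (95% interval -0.0642 to 0.168), and 0.0238 without LA rat 7 and 0.0932 without LA rat 1. Over the 4 targets brighter than the limit for dim genes, which leave out Ahrr, it was 0.0141 (95% interval -0.134 to 0.162). ALA minus LA rats gave -0.114 (95% interval -0.23 to 0.00177), with an upper bound below 0 without obese control 7 (-0.00188), ALA rat 3 (-0.0225) or 7 (-0.0155) or LA rat 1 (-0.0507) or 4 (-0.00133). A shared response and its absence cannot be told apart, because the interval against obese controls spans both.

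Other divisions of the same 16 arrays tested whether chance gives as many calls, with 100 divisions per comparison. For genes in obese against lean controls 1 of 100, the real one, gave 192, and the highest other gave 27. In ALA and LA rats against lean controls 1 of 100 gave 97 (highest other 2) and 1 of 100 gave 177 (highest other 1). This makes chance unlikely for these 3 numbers of genes, though 100 divisions cannot exclude it. For the diet comparisons the test says nothing about chance, since limma called 0 genes and 100 of 100 divisions give at least as many by construction. The highest other gave 1 on ALA, 208 on LA and 1 between the oils, where 918, 682 and 758 genes had an unadjusted p below 0.05. The division with 208 had obese controls 4, 5, 7 and 8 and LA rats 2, 5, 7 and 8 on the same side, which may point to a structure of the samples that was not tested.

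For lists, 2 of 100 divisions gave the 15 called in obese against lean controls, the real one included, with a highest other of 15. Chance is therefore unlikely for that number but not excluded. For the diets chance is not excluded either: 37 of 100 divisions gave the 10 lists called on ALA (highest other 14), 38 of 100 the 12 on LA (highest other 17), and 32 of 100 the 10 between the oils (highest other 15). Other divisions called a median of 7 lists in obese against lean controls, 7 on ALA, 10 on LA and 8 between the oils. Camera with the preset correlation thus called lists in arbitrary divisions too, and its adjusted p values alone do not show a shift.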
